A study of Homo sapiens with 79 samples.

How the data were processed

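The samples were 79 single cells of HT29, a human epithelial cell line from a colorectal adenocarcinoma. According to the labels, cDNA was made from total RNA on a Fluidigm C1 microfluidic system, which captures 1 cell per chamber, and libraries were made with the Nextera XT kit. No molecular identifiers are named in that protocol, so copies made by PCR were counted as reads. The treatment characteristic put 33 cells in the control group and 46 in the dasatinib group. A treatment protocol worded alike for both groups names a double thymidine block, which gathers cells at the start of S phase, and dasatinib at 100 nM. The titles carry a time of 12 hr. Whether that is time on dasatinib or time after the block, and whether control cells had the block alone, is not given in the sources used here, so what the ratios and cycle values compare is uncertain to that extent. No separate culture is named, so each group was treated as 1 sample and its cells were not treated as replicates.

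The authors deposited an RSEM gene table per cell, with 58302 gene models. Estimated counts (the expected count of RSEM) and TPM were both computed by the authors, per the file headers. STAR 2.5.3a, RSEM without a version and the build GRCh38 are named, per the submitters' processing notes. The annotation release and any read filter are not given in the sources used here. Over all gene models, a median of 1.96% of the expected counts per cell in the deposited tables were not whole, and 14.0% of those above 0, because RSEM divides reads that match more than 1 gene. The deposited TPM is corrected for gene length and sums to the same total in each cell. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned with certainty, and such genes carry that remark. Coordinates and overlaps come from GENCODE 29 on GRCh38, in which 58039 of the gene IDs were found.

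Expected counts were rounded to whole numbers per cell and summed over the cells of a group, so a deeply sequenced cell weighed more. The sums were divided by the group total and scaled to a total of 1000000 (CPM), and the main value of a gene was the log2 ratio of dasatinib over control. Exact Poisson intervals for sums, the exact conditional interval for a ratio of sums and exact Clopper-Pearson intervals for shares were used at the 95% level. The intervals for sums and ratios cover counting error only. Those for shares treat cells as independent draws and leave out any spread between cultures. A level of 0 was read against a floor of 3 counts over the group. With 1 sample per group there was no test, no p-value and no replicate check.

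Choices made before the data were examined were the filters, the gene lists, the rule for named genes and most alternatives. Cells needed at least 100000 counts and at least 2000 genes with an expected count of at least 1, and all 79 cells passed. No doublet caller was run on so few cells. No 2 cells had the same counts. Of the gene models, 21740 had a count in at least 1 cell. Genes were ranked if they had at least 20 CPM in a group and were detected in at least 25% of its cells. The log2 ratios of summed CPM, of mean TPM over cells with a pseudocount of 1, and of summed CPM without the cell holding most counts of the gene had to share a direction. The smallest of the 3 set the rank, and 12 genes per direction were named. From each list the 2 highest and 2 lowest members with at least 20 CPM in a group were named, together with a fixed set of kinases, cycle genes and reference genes. Some genes chosen by these rules are not reported here.

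For 41 gene lists, the median log2 ratio was taken over members with at least 5 CPM in a group, and 35 lists had at least 3 such members. The names of 2 list genes were not found in the files. Each median was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Genes of a list vary together within a cell, so a percentile describes these libraries and is not a test. A list score per cell was the mean of log2(TPM + 1) over all members. Genes per cell and shares of cells with cycle genes were also taken after thinning each cell to 1000000 counts, which left out 1 control cell. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. In R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 gave alternative scaling factors for the group sums and no test.

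The ratio and its interval were checked on simulated counts for the dasatinib over control comparison. With Poisson counts, 94.8% of the intervals of 5786 genes held the simulated log2 ratio. When a spread between cells was added, 8.38% did, since the interval leaves that spread out. With that spread, genes simulated with 2-fold and 8-fold differences (50 each) gave median absolute log2 ratios of 0.98 and 2.87. The simulated direction was found in all 3 estimates for 76% of genes at 1.5-fold, 88% at 2-fold, 96% at 4-fold and 92% at 8-fold. In both simulations, all 24 named genes were genes simulated as different. A list of 20 genes simulated as different lay at percentile 100 in both, and unchanged lists lay at 13.4 and 82.5. The spread was drawn independently for each gene and cell and was not fitted to these data. No simulated cell was of unusual quality, and no genes varied together within a cell. The simulations therefore do not show how the naming rule or the percentiles perform where such cells or genes occur.

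Depth ranged from 959338 to 7112800 counts per cell. Alternatives covered the weight of cells, the pseudocount, scaling, the cell filter, cells with many detected genes, thinning, filters on low genes and detection limits. Values without 7 cells whose share of mitochondrially encoded counts was at least 20% or under 1%, and list medians without each cell in turn, were added after the data had been seen. The titles hold running library numbers, 135 to 168 for control and 89 to 134 for dasatinib, with 0 control libraries inside the dasatinib range. Preparation and treatment therefore cannot be told apart.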

Results

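Single-cell transcriptomes of HT29, an epithelial cell line from a human colorectal adenocarcinoma, were measured in 33 control cells and 46 cells labelled as treated with dasatinib. Dasatinib is an inhibitor of SRC family kinases, of ABL1 and ABL2 and of several receptor kinases. Control cells held 959338 to 5623786 counts (median 2516025) and dasatinib cells 1218630 to 7112800 (median 2794536), for sums of 83619921 and 143048014 counts. A median of 8297 genes was detected per control cell (range 3112 to 10021) and 8094 per dasatinib cell (3323 to 9889). After thinning to 1000000 counts the medians were 7865 in 32 control cells (SD over cells 1725) and 7658 in 46 dasatinib cells (SD 1611), a difference smaller than the spread over cells.

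Transcripts of the mitochondrial genome made up 12.5% of the control sum and 13.97% of the dasatinib sum. The median share per cell was 7.12% in control (range 3.01 to 56.7%) and 7.31% in dasatinib (0.020 to 79.1%). In 4 control cells (12, 40, 41 and 52) and 2 dasatinib cells (29 and 47) the share was at least 20%, and these cells had few detected genes. Dasatinib cell 87 had almost no mitochondrial transcripts.

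**Figure D1:**
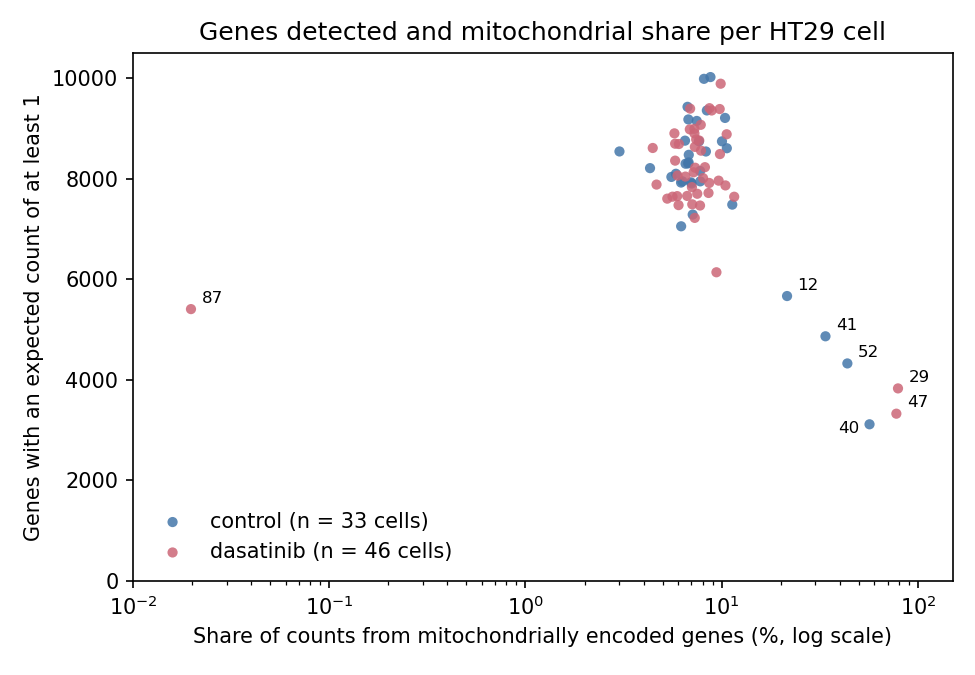
Each point is 1 HT29 cell; the horizontal axis is the share of its counts from mitochondrially encoded genes in percent on a log scale, and the vertical axis is the number of genes with an expected count of at least 1. Most of the 33 control and 46 dasatinib cells overlap near 7%, while the 7 numbered cells lie at 20% or more or under 1%.

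The study asked which pathways could let colorectal cancer cells withstand dasatinib, so the dasatinib cells were compared with the control cells. Each group is 1 sample without replicates, and intervals of sums and ratios cover counting error only. Over 10079 genes with at least 5 CPM in a group, the median log2 ratio of dasatinib over control was 0.013 and the interquartile range was -0.33 to 0.40. Pearson's r of log2 summed CPM across these genes, which are not independent replicates, was 0.917.

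LAMB3, a laminin chain of the epithelial basement membrane, was among the genes higher in dasatinib, with 3.71 CPM in control and 44.6 CPM in dasatinib (12.02-fold; log2 ratio 3.59, interval 3.42 to 3.76). CDKN1C, an inhibitor of cyclin-dependent kinases, had 0.742 CPM in control and 36.7 CPM in dasatinib (log2 ratio 5.63, interval 5.27 to 6.01). KLHL24, a kelch-like protein, was 7.03-fold higher (9.45 and 66.4 CPM), and PRR15L had 19.6 CPM in control and 125.4 CPM in dasatinib (log2 ratio 2.68). The actin-binding calponin CNN3 had a log2 ratio of 4.13, the LIM domain protein LMCD1 3.15 and the membrane transporter SLC4A11 3.18. The ratios were 3.73 for ZFP1, 4.58 for ZNF621, 4.29 for ZNF20 and 3.31 for HIVEP1, which encode zinc finger proteins. ZNF20 shares exons with the readthrough model ZNF625-ZNF20, HIVEP1 with AL157373.2 and LMCD1 with a gene on the other strand, so their reads may be partly shared. LAMB3 holds the microRNA gene MIR4260, and PRR15L lies inside a gene on the other strand.

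Single cells carried much of these sums. Dasatinib cell 26 held 92.8% of the CDKN1C counts of its group, and the log2 ratio without it was 1.89. Without dasatinib cell 29, which had a mitochondrial share over 20%, the values were 2.25 for ZFP1, 2.41 for LAMB3, 2.18 for SLC4A11 and 1.75 for CNN3. Leaving out dasatinib cell 47, also over 20%, gave 2.28 for ZNF621 and 1.70 for PRR15L. Dasatinib cell 3 was the top cell of KLHL24, LMCD1, ZNF20 and HIVEP1, which had log2 ratios of 2.12, 2.14, 3.64 and 1.65 without it. The top cell held 66.0% of the ZFP1, 80.6% of the ZNF621 and 69.7% of the HIVEP1 counts in dasatinib. At 22.4, 23.8 and 20.5 CPM these genes passed the level limit only through that cell. Detection differed little for ZFP1 (24.2% of control and 28.3% of dasatinib cells) and HIVEP1 (33.3% and 37.0%). It differed more for LMCD1 (15.2% and 43.5%) and ZNF20 (9.09% and 32.6%). LAMB3 lies at chromosome 1, positions 209614870 to 209652466, CDKN1C at chromosome 11, 2883213 to 2885773, and KLHL24 at chromosome 3, 183635568 to 183684477 (GRCh38).

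MLKL and RIPK3, the membrane-permeabilising effector and the kinase of necroptosis, were both among the genes lower in dasatinib. MLKL had 67.1 CPM in control and 8.82 CPM in dasatinib (log2 ratio -2.93, interval -3.02 to -2.84), and RIPK3 had 21.3 and 2.10 CPM (-3.35, -3.53 to -3.17). The kinase SGK3 was 5.92-fold lower in dasatinib (24.6 and 4.16 CPM), and the semaphorin and VEGF co-receptor NRP1 4.07-fold lower (24.4 and 5.998 CPM). PLOD2, a collagen lysyl hydroxylase, had a log2 ratio of -2.71, the CDC42-binding kinase CDC42BPB -2.28 and the homeobox gene HOXB3 -2.20. Among long noncoding transcripts, OLMALINC had -2.83 and MIR222HG -2.77.

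The unclassified model AC105235.1 (-4.93) lies inside PTK2, and AC008560.1 (-2.96) shares exons with TRAPPC13, so reads of either cannot be assigned with certainty. The same holds for SGK3, which overlaps C8orf44, for HOXB3, which overlaps HOXB4, HOXB6 and antisense genes, for RIPK3, which overlaps AL096870.1, and for CDC42BPB and NRP1, which have partners on the other strand. Control cell 52, with a mitochondrial share over 20%, held 63.5% of the MLKL counts and 67.0% of the RIPK3 counts of its group. Without it the log2 ratios were -1.58 for MLKL, -1.85 for RIPK3, -1.88 for OLMALINC, -1.87 for MIR222HG and -3.73 for AC105235.1. Without control cell 41 the values were -1.98 for AC008560.1 and -1.67 for HOXB3. Leaving out control cell 12 gave -2.02 for SGK3 and -1.31 for CDC42BPB, and leaving out control cell 40 gave -1.28 for PLOD2, whereas NRP1 had -1.71 without control cell 39. MLKL lies at chromosome 16, positions 74671855 to 74700960, RIPK3 at chromosome 14, 24336021 to 24340045, and NRP1 at chromosome 10, 33177492 to 33336262.

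**Figure D2:**
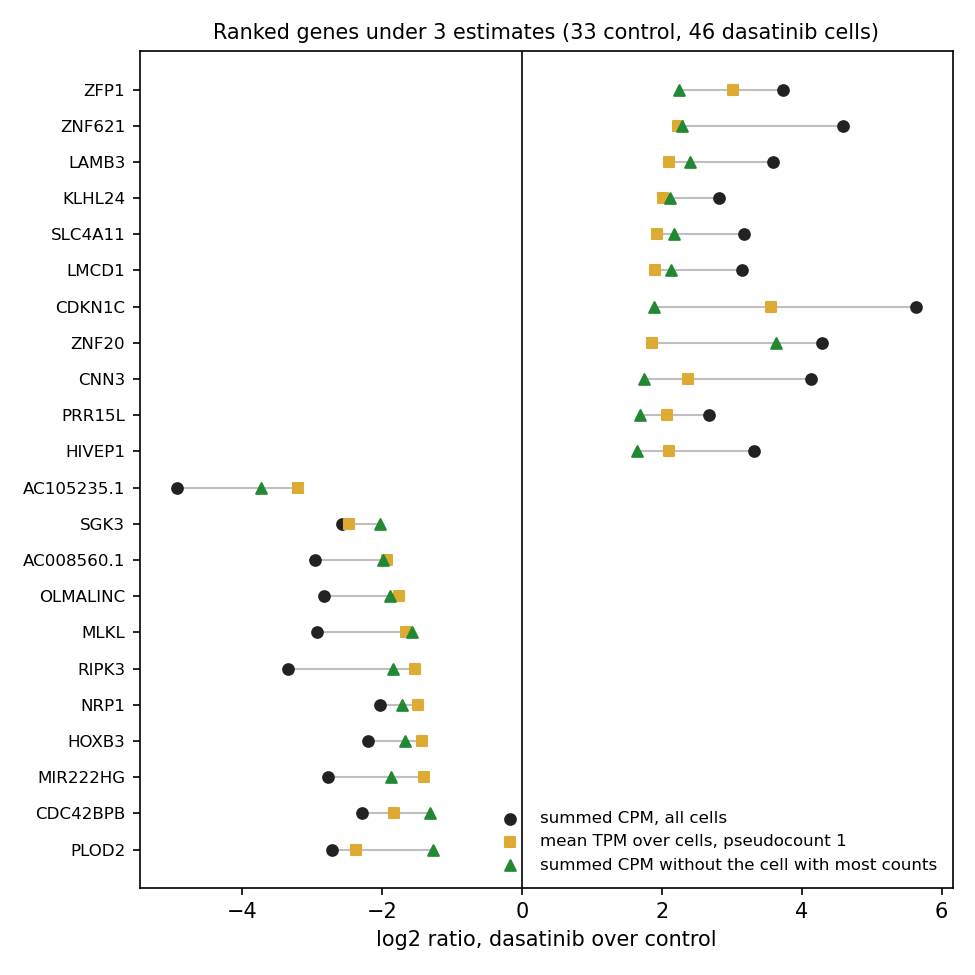
The horizontal axis is the log2 ratio of dasatinib over control for the ranked genes named above, as summed CPM over all cells (circles), mean TPM over cells with a pseudocount of 1 (squares) and summed CPM without the cell holding most counts of the gene (triangles). All 3 estimates lie on 1 side of 0 for each gene because the ranking rule required it. The circle lies farthest from 0, as for CDKN1C at 5.63 against 1.89 without 1 cell.

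Across the 24 ranked genes, the top cell held 23.3 to 92.8% of the counts of its group, and for 17 genes that cell had an unusual mitochondrial share. Without the 7 cells of unusual mitochondrial share, all 24 kept their direction and 21 kept an absolute log2 ratio of at least 1, among them AC105235.1 at -1.43 and PRR15L at 1.30. HOXB3 (-0.92), MIR222HG (-0.89) and CDC42BPB (-0.38) were the exceptions. The ranking rule had already required each direction to hold without the top cell, which for 17 genes was among those 7 cells. The kept directions were therefore largely fixed in advance and are no test.

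Kinases bound by dasatinib had no common direction. Among 16 of these genes over 5 CPM, 7 were higher and 9 lower in dasatinib, and the median log2 ratio was -0.092, at percentile 20.2 of matched random lists. YES1, the SRC family member with the highest level among those named, was 1.29-fold lower in dasatinib (log2 ratio -0.37, interval -0.41 to -0.34). SRC itself was at 6.39 and 9.79 CPM (0.62, 0.47 to 0.76), FYN at 9.75 and 8.48 CPM (-0.20, with 0.16 without control cell 18 and -1.33 without the 7 cells of unusual mitochondrial share) and ABL2 at 2.42 and 1.76 CPM (-0.46, and -0.078 without control cell 36). ABL1 was 3.60-fold lower in dasatinib (12.2 and 3.38 CPM) and 2.55-fold lower without control cell 44. RIPK2 had a log2 ratio of -0.42.

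The level of EPHA2 was 36.6 CPM in control and 26.9 CPM in dasatinib (-0.44), but its log2 ratio was 0.35 in mean TPM and 0.14 without control cell 52. Likewise DDR1 (29.3 and 23.4 CPM, -0.32) had 0.45 in mean TPM and 0.41 without control cell 41. LYN had 0 counts in control and 0.951 CPM in dasatinib, 26.5-fold higher when control is set to a floor of 3 counts over the group (lower interval limit of the log2 ratio 4.41), with 85.3% of its counts in dasatinib cell 6. LCK had 1.27 CPM in control, all from control cell 11, and 1 count in dasatinib, 60.4-fold lower with dasatinib set to the same floor. The list median without control cell 18 was 0.076, at percentile 47.8. YES1 overlaps a gene on the other strand, as CDKN1A, VIM and GAPDH do, and DDR1 holds the microRNA gene MIR4640.

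Genes of early G1 and quiescence were higher in dasatinib, with 14 of 16 members higher and a median log2 ratio of 0.46, at percentile 99.8. CDKN1C had the highest ratio, followed by the antiproliferative factor BTG1 (27.7 and 61.6 CPM, 1.15, and 0.32 without dasatinib cell 26). The lowest were CCND1, the cyclin that drives early G1 (1.45-fold lower in dasatinib, -0.54), and the CDK inhibitor CDKN2D (-1.44). The mean list score per cell was 2.17 ± 0.81 (SD, 33 cells) in control and 2.53 ± 0.74 (SD, 46 cells) in dasatinib, so the groups differed by less than the spread over cells. Without the 7 cells of unusual mitochondrial share the list median was 0.30, at percentile 96.8, and without control cell 36 it was 1.02.

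FOXO target genes, which share CDKN1B, CCNG2, TXNIP and YPEL3 with that list, had a median log2 ratio of 0.43 at percentile 98.9, with 8 of 13 members higher. KLHL24 (2.81) and TXNIP, an inhibitor of thioredoxin (120 and 241 CPM, 1.00), were the highest, and RICTOR (-0.23) and GADD45A (-0.99) the lowest. The FOXO median was 0.15 at percentile 80.6 without dasatinib cell 26 and 0.23 at percentile 85.7 without the 7 cells of unusual mitochondrial share. The early G1 median without the 4 shared genes was 0.45. For p53 target genes the median was 0.31 (percentile 93.5; 11 of 17 higher). The highest were BTG2 (1.93, and 0.41 without dasatinib cell 26) and PLK3 (1.63), and the lowest MDM2 (-0.44, and 0.11 without control cell 36) and AEN (-0.80). The p53 median was 0.017 without dasatinib cell 26 and 0.40 at percentile 98.04 with cells thinned to the same depth. CDKN1A, the p53-responsive CDK inhibitor, had 51.9 and 67.0 CPM (0.37), and -0.72 without that cell.

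Genes of S phase entry and of mitosis had list medians near 0, though single cells moved both lists. The G1/S list had a median log2 ratio of -0.0083 (percentile 50.1; 22 of 45 higher), and the G2/M list 0.017 (percentile 81.4; 30 of 56 higher). The G1/S median was -0.14 at percentile 3.81 without dasatinib cell 87, and -0.079 at percentile 5.02 without the 7 cells of unusual mitochondrial share. The G2/M median was 0.26 at percentile 100.0 without control cell 3, 0.17 at percentile 99.98 without the 3 cells with unusually many genes, and -0.087 at percentile 23.2 without dasatinib cell 6. The extremes were CCNE2 (0.81, and -0.87 without dasatinib cell 87), MCM2 (0.61), CLSPN (-0.82) and CDT1 (-1.11) for G1/S, and BUB1, TACC3 (1.06), CDK1 (-0.62) and TTK (-0.72) for G2/M. BUB1 had a log2 ratio of 1.46, and of 0.18 without dasatinib cell 29. Without the 7 cells of unusual mitochondrial share, BUB1 had -0.016 and TTK 0.21. MKI67 was at 264 CPM in control and 182 CPM in dasatinib (-0.54), and at -0.059 without the 7 cells of unusual mitochondrial share. TOP2A was at 243 and 222 CPM (-0.13, and 0.47 without control cell 40), and cyclin B1 (CCNB1) at 654 and 777 CPM (0.25).

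At least 33.3% of the G2/M list was detected in 31 of 32 thinned control cells (96.9%, interval 83.8 to 99.9%) and 45 of 46 dasatinib cells (97.8%, 88.5 to 99.9%). For the G1/S list the numbers were 31 of 32 (96.9%) and 41 of 46 (89.1%, 76.4 to 96.4%), and the intervals overlapped. Without thinning, every cell of both groups passed for both lists. Control cells 36 and 14, with G2/M scores of 2.39 and 7.36, both passed after thinning. The share thus lies near its ceiling, so it does not place a cell in a phase and can hardly show a group difference. Within 5 percentage points of the boundary lay 0 control and 2 dasatinib cells for G2/M genes and 2 and 1 for G1/S genes. The mean share of the list detected was 75.6 ± 18.2% (SD) in control and 75.2 ± 19.5% in dasatinib for G2/M genes, and 75.3 ± 19.7% and 72.9 ± 22.8% for G1/S genes. Replication-dependent histone genes had a median log2 ratio of 0.24 (percentile 78.9; 7 of 10 higher), with HIST1H2BD at 1.24 (0.53 without dasatinib cell 26), HIST1H4C at 0.17 (-0.092 without dasatinib cell 3) and HIST1H2AC at 0.15 (-0.47 without dasatinib cell 26). The histone median was -0.051 without the 7 cells of unusual mitochondrial share.

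Goblet cell markers, the genes of mucus-secreting intestinal cells, were higher in the dasatinib sum. All 5 members over 5 CPM were higher, with a median log2 ratio of 1.61 at percentile 100. TFF3, a secreted trefoil peptide, had 9.26 CPM in control and 44.9 CPM in dasatinib (2.28), SPDEF, a transcription factor of secretory cells, 15.1 and 50.7 CPM (1.74), the mucin MUC5AC 0.60 and the disulfide isomerase AGR2 0.53. Dasatinib cell 26 held 75.8% of the TFF3 counts, and cell 29 held 59.5% of the SPDEF counts, with log2 ratios of 0.29 and 0.51 without them. The goblet median was 0.66 without dasatinib cell 26 and 0.60 without the 7 cells of unusual mitochondrial share. The mean goblet score per cell was 1.07 ± 0.62 (SD) in control and 1.27 ± 0.60 in dasatinib, a difference smaller than the spread over cells.

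Enterocyte markers had a median of 0.64 at percentile 98.3 from 3 members, namely CA2 (1.82, and 1.03 without dasatinib cell 87), VIL1 (0.64) and KRT20 (-0.051, and 0.25 without control cell 36). Without cell 87 the list median was 0.50, at percentile 96.6. Stem cell markers had a median of 0.11 (percentile 66.8; 4 of 7 higher), with SLC12A2 at 0.37, CDCA7 at -0.19 and RNF43 at -0.37 (0.10 without control cell 40). That median was -0.028 without dasatinib cell 44. The Paneth cell list had LYZ alone over 5 CPM, at 4327 CPM in control and 4816 CPM in dasatinib (0.15). LYZ is also in the immune cell list, which had a median of -0.32 (percentile 13.7; 1 of 4 higher) with CD68 at -0.52, and -0.61 at percentile 3.25 without dasatinib cell 3.

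No enteroendocrine, fibroblast, or red blood cell and serum marker reached 5 CPM. Their sums were 1.28 and 5.48 CPM for enteroendocrine markers, 2.62 and 2.99 CPM for fibroblast markers, and 0.969 and 0.385 CPM for red blood cell and serum markers. ESAM was the 1 endothelial marker over the limit (87.8 and 80.1 CPM, -0.13, and 0.0017 without control cell 28). Liver, kidney and neuron markers had 2, namely MBP (0.26, and -0.16 without dasatinib cell 3) and TTR (21.5 and 5.53 CPM, -1.96), and control cell 36 held 99.8% of the TTR counts of its group, so that the TTR ratio was 7.22 without it. The epithelial marker EPCAM was at 947 and 955 CPM (0.013, and -0.12 without the 7 cells of unusual mitochondrial share). The mesenchymal marker VIM was at 1.10 and 1.20 CPM (0.13, interval -0.25 to 0.51, and -0.66 without dasatinib cell 6). VIM was detected in 1 control and 4 dasatinib cells, too few to read a difference from.

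The interferon, immediate early and ATF4 lists had higher medians in dasatinib, which fell near or below 0 without 1 dasatinib cell. Summed over all members, the interferon list was at 1330 CPM in control and 1303 CPM in dasatinib. The totals were 1038 and 1151 CPM for the immediate early list and 2858 and 2802 CPM for the ATF4 list. Interferon-stimulated genes had a median log2 ratio of 0.57 at percentile 100.0 (16 of 23 higher), with OAS1, a sensor enzyme of viral RNA, at 22.5 and 60.1 CPM (1.42, and 0.74 without dasatinib cell 46), IRF7 at 0.80, ISG20 at -0.87 (-0.22 without control cell 36) and OAS3 at -0.96 (-0.21 without control cell 41). Without dasatinib cell 46 the median was 0.056 at percentile 61.4. The immediate early and stress response list had a median of 0.63 at percentile 100.0 (10 of 18 higher), with BTG2 and BTG1 highest, both carried by dasatinib cell 26 as given above, and EGR1 (-0.71) and IER3 (-1.54) lowest. Without dasatinib cell 3 that median was -0.12 at percentile 15.8. ATF4 and unfolded protein response genes had 0.23 at percentile 98.5 (11 of 19 higher), and -0.063 without dasatinib cell 3. The highest were PPP1R15A (3.76-fold higher, 1.91, and -0.15 without cell 3) and HSPA5 (0.57, and -0.051 without cell 3), and the lowest CEBPB (-0.56) and SDF2L1 (-0.76).

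NF-kB target genes had a median of 0.069 (percentile 53.9; 6 of 10 higher), and -0.17 without dasatinib cell 87. CXCL1 (1.54, and 0.77 without dasatinib cell 14) and NFKBIA (1.24, and 0.71 without dasatinib cell 3) were highest. For NFKBIA the mean over cells of log2(TPM + 1) differed by -0.19, the other direction. NFKBIZ (-0.75) and the chemokine CXCL8 (26.99 and 6.14 CPM, -2.14, and -1.20 without control cell 41) were lowest. Heat shock genes had a median of 0.0034 (percentile 71.5; 7 of 13 higher), with BAG3 at 0.68, HSPA1B at 0.58, HSPE1 at -0.60 and HSPA4L at -0.62. Without dasatinib cell 3 it was -0.088.

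**Figure D3:**
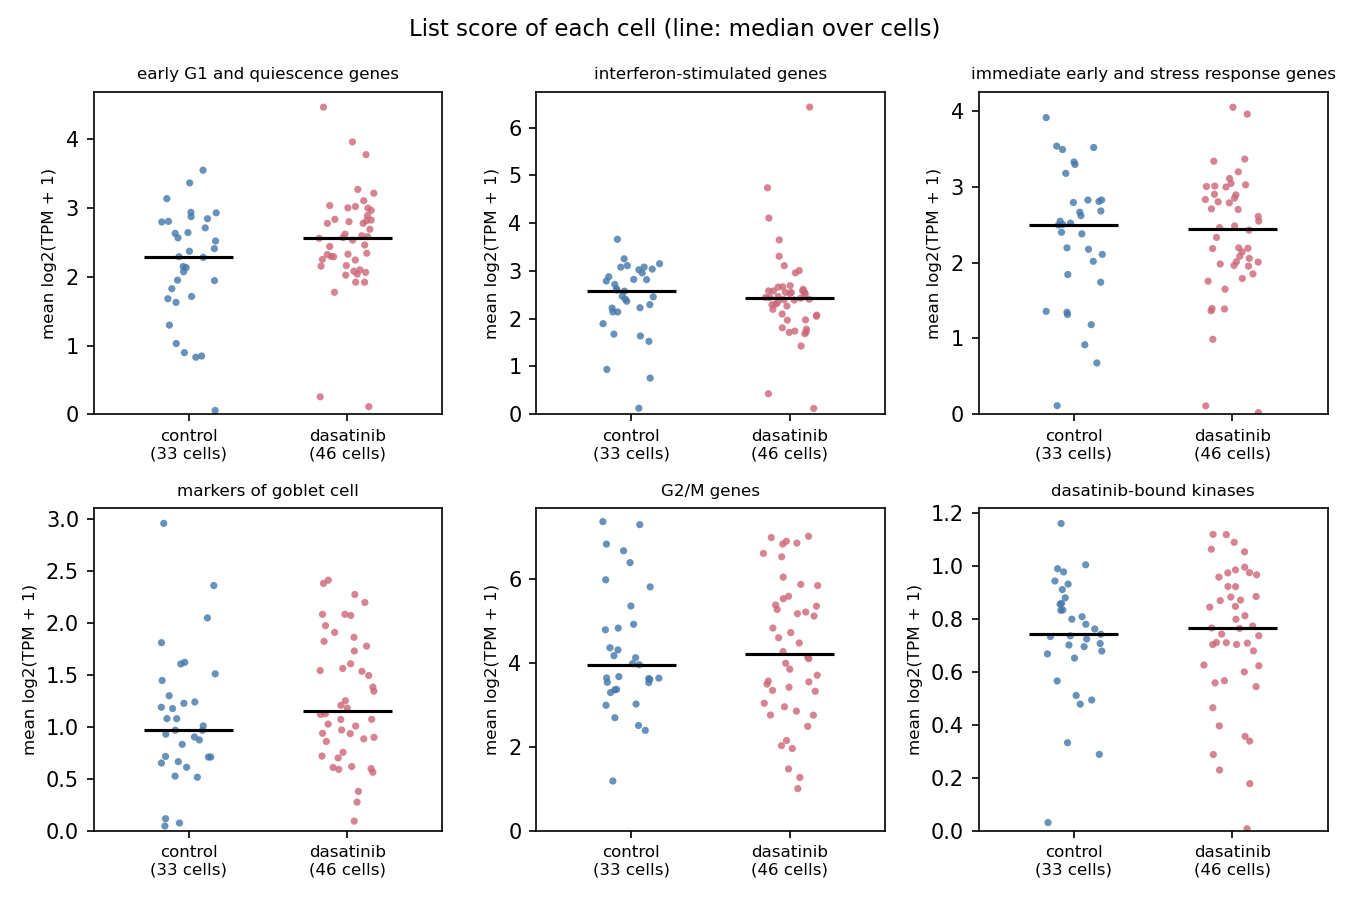
Each point is the score of 1 cell, the mean of log2(TPM + 1) over the members of a list on the vertical axis, for 6 lists in 33 control and 46 dasatinib cells, with a line at the median. The medians are 2.29 and 2.57 for early G1 and quiescence genes and 2.58 and 2.44 for interferon-stimulated genes, where dasatinib cell 46 stands at 6.43.

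Adhesion and growth factor signalling genes had medians near 0 in the sums of all cells, and some of these medians turned on few cells. Focal adhesion genes and SRC substrates had 0.0093 (percentile 53.9; 16 of 29 higher), with 0.23 at percentile 95.6 in mean TPM and 0.16 at percentile 89.9 with cells thinned to the same depth. Within them the scaffold NEDD9 was 3.95-fold higher in dasatinib (8.78 and 34.7 CPM, log2 ratio 1.98) and CAV1 1.80-fold higher. PXN (-0.72) and CRKL (-0.75) were lowest, with -0.20 and -0.024 without control cell 52. PXN had 0.23 in mean TPM, and CRKL had 0.040 without the 7 cells of unusual mitochondrial share. YAP and TEAD target genes had 0.081 (percentile 49.5; 7 of 13 higher), and -0.45 at percentile 3.37 without dasatinib cell 8. GADD45B had 3.38, and 1.13 without dasatinib cell 3, followed by TEAD1 (0.27), and MYOF (-0.94, and -0.16 without control cell 41) and NT5E (-0.98) were lowest. MAPK output genes had -0.087 (percentile 24.2; 7 of 17 higher), and -0.42 at percentile 0.165 without dasatinib cell 26. The MAPK median was 0.27 at percentile 95.6 without the 7 cells of unusual mitochondrial share, and -0.25 at percentile 0.205 as a mean over cells of log2(TPM + 1), so its direction is not settled here. ETV5 (1.06, with -0.41 in mean TPM and 0.38 without dasatinib cell 3) and FOSL1 (0.61, and -1.11 without dasatinib cell 3) were highest, and SPRED1 (-1.29, with -0.054 without control cell 52 and 0.27 without the 7 cells of unusual mitochondrial share) and IER3 lowest.

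Receptor tyrosine kinases and their ligands had a median of 0.0080 (percentile 39.9; 10 of 20 higher), and -0.21 without dasatinib cell 3. That median was 0.37 at percentile 98.1 without the 7 cells of unusual mitochondrial share and 0.32 at percentile 95.96 in mean TPM. EGFR had 22.7 CPM in control and 11.4 CPM in dasatinib (-0.99, interval -1.09 to -0.90) and -0.88 without its top cell, control cell 22. ROR1 was at -0.50. IGF2 had 10.6 and 29.7 CPM (1.49, and 0.52 without dasatinib cell 29), and the EGFR ligand EREG 80.4 and 132.5 CPM (0.72, with -0.79 without dasatinib cell 3 and 1.61 without the 7 cells of unusual mitochondrial share). WNT target genes had 0.033 (percentile 52.8; 5 of 9 higher), with the transcription factor SOX4 2.69-fold higher (71.0 and 191 CPM, 1.43, and 0.81 without dasatinib cell 26), CD44 at 0.033 (-0.035 without dasatinib cell 35), RNF43 at -0.37 and ZNRF3 at -0.93. Without control cell 40 RNF43 had 0.10, and without control cell 52 ZNRF3 had 0.23. The WNT median was 0.40 at percentile 99.95 with the median over cells of log2(TPM + 1).

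Epithelial genes had a median of 0.020 (percentile 70.2; 11 of 20 higher), with OVOL1 at 1.63 (0.78 without dasatinib cell 87), ESRP2 at 1.25, CDH1, which encodes E-cadherin, at -0.28 (0.071 in mean TPM), and MARVELD2 at -0.86 (-0.066 without control cell 41). The epithelial median was 0.22 at percentile 98.1 in mean TPM. Mesenchymal genes over 5 CPM were 3, with a median of -0.50 at percentile 4.80, and -0.67 at percentile 0.435 without the 7 cells of unusual mitochondrial share. S100A4 had 388 and 275 CPM (-0.50) and TGFBI 60.0 and 32.3 CPM (-0.90). Actin cytoskeleton and SRF target genes had 0.035 (percentile 88.2; 14 of 22 higher), led by CNN3 and TPM1 (0.53), with ZYX (-0.50) and MYH9 (-0.56) lowest. The actin list median was -0.088 without the 7 cells of unusual mitochondrial share. ACTB was at 9133 and 9847 CPM (0.11) and GAPDH at 5883 and 6154 CPM (0.065), with -0.015 and -0.054 without the 7 cells of unusual mitochondrial share. S100 and annexin genes had -0.13 (percentile 20.9; 5 of 16 higher, and -0.16 at percentile 1.16 as a mean over cells of log2(TPM + 1)), with ANXA10 2.22-fold higher (37.1 and 82.5 CPM), S100A2 at 0.088 (-0.16 without dasatinib cell 4), ANXA3 at -0.34 and S100A4 lowest.

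**Figure D4:**
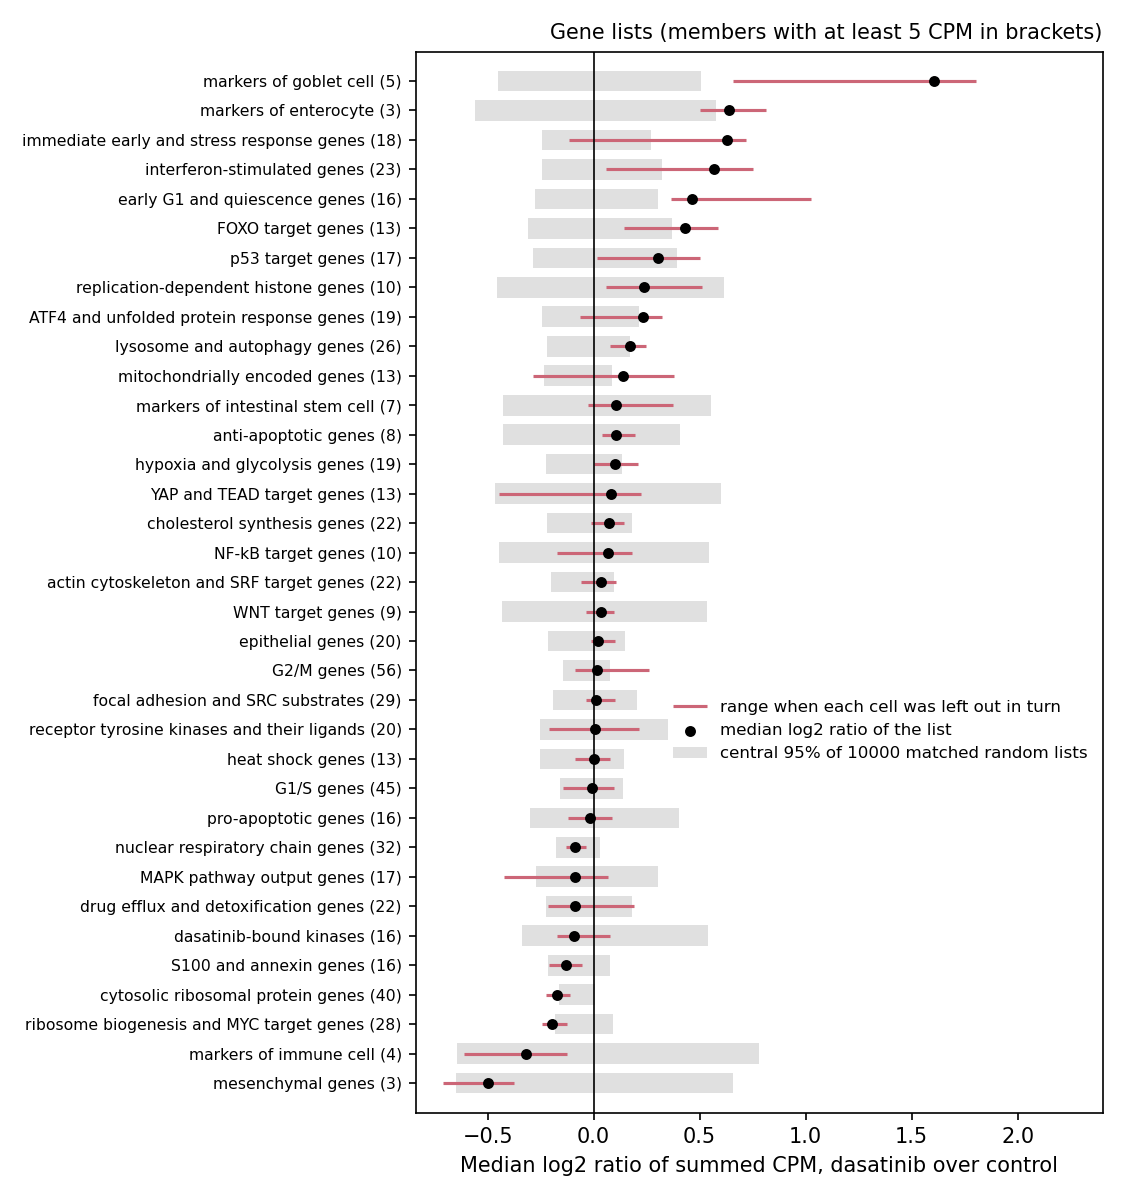
The horizontal axis is the median log2 ratio of dasatinib over control for 35 gene lists (points), with the range when each cell was left out in turn (coloured lines) and the central 95% of 10000 matched random lists (grey bars). The interferon-stimulated genes range down to 0.056 and the immediate early genes down to -0.12, while the early G1 and quiescence genes stay at 0.36 or above.

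Ribosome genes were slightly lower in the dasatinib sum, near the edge of the matched random lists. Of 40 cytosolic ribosomal protein genes, 33 were lower, with a median log2 ratio of -0.17 at percentile 1.15, from RPL3 (0.20) and RPS2 (0.15) to RPS24 (-0.43) and RPL37 (-0.44). Many ribosomal protein genes have processed pseudogenes with which they may share reads. Ribosome biogenesis and MYC target genes had -0.20 at percentile 1.68 (20 of 28 lower), with ODC1, the first enzyme of polyamine synthesis, at 0.52, RRP9 at 0.43, WDR43 at -0.60 (0.22 without the 7 cells of unusual mitochondrial share) and the chaperonin HSPE1 at 900 and 595 CPM (-0.60). Without dasatinib cell 29 these list medians were -0.11 at percentile 2.10 and -0.13 at percentile 2.89. Random lists matched to them had medians of -0.082 and -0.052 over all cells. Genes at these levels thus lay slightly below 0 as a whole, and the counts of lower members partly share that shift. Ribosomal protein genes came within the central 95% with the stricter cell filter (-0.068, percentile 5.47) and without the 7 cells of unusual mitochondrial share (-0.13, percentile 3.46). Ribosome biogenesis genes did so with the stricter filter (-0.10, percentile 2.72), without the 3 cells with unusually many genes (-0.16, percentile 5.85), and for members over 20 CPM (percentile 2.67).

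Mitochondrially encoded genes had a median of 0.14 at percentile 99.5 (8 of 13 higher), but -0.28 without dasatinib cell 29 and -0.13 in mean TPM. MT-ND6 (0.47) and MT-ND4L (0.35, and -0.075 without dasatinib cell 47) were highest. MT-ND3 (-0.33) and MT-ATP8 (-0.35) were lowest, with 0.12 and 0.048 without control cell 52. Nuclear respiratory chain genes had -0.086 (percentile 41.5; 15 of 32 higher), with NDUFA9 at 0.63, UQCRC1 at 0.29, NDUFA4 at -0.39 and cytochrome c (CYCS, 903 and 598 CPM) at -0.59. Hypoxia and glycolysis genes had 0.099 (percentile 93.5; 13 of 19 higher), 0.21 at percentile 99.4 without control cell 36 and -0.014 without the 7 cells of unusual mitochondrial share. The vasodilator peptide ADM had 8.44 and 322 CPM (5.25), of which dasatinib cell 3 held 95.6%, leaving 0.81 without it, and ENO2 had 1.70, ALDOC -0.40 (0.80 without control cell 36) and P4HA1 -0.93.

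Cholesterol synthesis genes had a median of 0.072 (percentile 79.4; 12 of 22 higher), with HMGCS1 at 1.45 (0.45 without dasatinib cell 3) and HSD17B7 at -0.65 (-0.023 without control cell 36). Lysosome and autophagy genes had 0.17 (percentile 97.3; 16 of 26 higher), with ATG16L1 at 1.43, ATP6V1H at 0.59, LAMP1 at -1.18 (-0.53 without the 7 cells of unusual mitochondrial share) and ATG9A, a membrane protein of autophagosome formation, at 30.3 and 11.96 CPM (-1.34). The lysosome median was 0.079 without dasatinib cell 26 and 0.29 at percentile 99.1 as a mean over cells of log2(TPM + 1).

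Drug efflux and detoxification genes had a median of -0.089 (percentile 24.9; 10 of 22 higher), with 0.19 at percentile 97.2 without control cell 36 and -0.25 at percentile 0.1 without the 7 cells of unusual mitochondrial share. The efflux pump ABCG2 had 71.0 CPM in control and 28.3 CPM in dasatinib (-1.33, interval -1.38 to -1.27), and -0.43 without control cell 41. AKR1C1 had -2.66, and -0.57 without control cell 36; it has close paralogs with which it may share reads. ALDH3A1 had 1.51 (0.74 without dasatinib cell 6) and CYP3A5 0.78 (0.032 without dasatinib cell 3). Anti-apoptotic genes had 0.10 (percentile 67.9; 5 of 8 higher), and 0.40 at percentile 96.4 without the 7 cells of unusual mitochondrial share, with BAG3 highest, BIRC2 at 0.49 (-0.0062 without dasatinib cell 3 and 1.17 without the 7 cells of unusual mitochondrial share), BAG1 at -0.083 and CFLAR at -0.58.

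Pro-apoptotic genes had a median of -0.019 (percentile 35.5; 7 of 16 higher), with PMAIP1 2.45-fold higher in dasatinib (11.04 and 27.1 CPM) and BAD at 0.53. BMF had 0 counts in control and 915 in dasatinib, 86.6% of them in dasatinib cell 26, and was left out of that median, which was -0.017 with BMF at the floor of 3 counts. It was looked at because of that 0, after its values were seen. Over all 35 lists with at least 3 members, 10 had medians outside the central 95% of matched random lists. Among those 10, the interferon-stimulated, immediate early, FOXO target, ATF4, enterocyte, ribosome biogenesis and mitochondrially encoded lists came within or to the other side of that range without 1 cell.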

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

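No paired analysis was possible because numbers in the titles only name cells and no test was run. Values without the 7 cells of unusual mitochondrial share, and those without each cell in turn, were chosen after seeing the data. The cause of each shift below was not tested, except that a leave-one-out value shows what 1 cell carried. Keeping all cells gave the reported values, since no cell was filtered. The edgeR and DESeq2 factors moved log2 ratios by 0.0052 and -0.0055. Depth limits genes with few counts, and intervals of sums and ratios leave out the spread between cells. Of 558 alternative values for 35 list medians, 425 moved by less than the spread of matched random lists. The sign was the other one for 78 values, among them 10 of lists outside the central 95%. Of 519 values for 40 named genes, 232 lay within the counting interval and 287 outside. For the 24 ranked genes, 297 of 312 values kept the reported direction. The ranking rule had already required that direction in mean TPM and without the top cell. Keeping all cells and rescaling the sums could hardly turn it, so part of this count was fixed in advance. The median log2 ratio over all genes was 0.10 with mean TPM and a pseudocount of 0.1. The interquartile range of log2 ratios was 0.36 with the median over cells of log2(TPM + 1).

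Goblet cell markers had 0.98 with mean TPM and a pseudocount of 1, 1.05 with 0.1, 0.44 with the mean over cells of log2(TPM + 1), 0.21 with its median, 0.70 with the stricter cell filter, 0.93 with thinned cells, 0.60 without the cells of unusual mitochondrial share, 0.60 with no filter on low members, and 0.66 to 1.80 with each cell left out. Enterocyte markers had 0.28 with the mean of log2(TPM + 1). Dasatinib-bound kinases had 0.30 and 0.37 with mean TPM and pseudocounts of 1 and 0.1, and -0.40 for members over 20 CPM. FOXO target genes had 0.0 with the median of log2(TPM + 1), 0.23 without the cells of unusual mitochondrial share and 0.15 to 0.58 with each cell left out.

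For mean TPM with pseudocounts of 1 and 0.1, the ATF4 list had 0.11 and 0.11, cytosolic ribosomal proteins -0.11 and -0.11, mitochondrially encoded genes -0.13 and -0.13, ribosome biogenesis genes -0.077 and -0.078, immediate early genes 0.36 and 0.37, and G2/M genes 0.13 and 0.13. For the mean over cells of log2(TPM + 1), the ATF4 list had -0.048, interferon-stimulated genes 0.13, ribosomal proteins -0.059, mitochondrially encoded genes -0.33 and immediate early genes 0.18. The median over cells of log2(TPM + 1) gave 0.0 for the ATF4, interferon and immediate early lists, -0.068 for ribosomal proteins, -0.049 for mitochondrially encoded genes, -0.12 for ribosome biogenesis and 0.20 for early G1 genes.

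Under the stricter cell filter, which left out 3 cells, ribosomal proteins had -0.068, mitochondrially encoded genes -0.69, ribosome biogenesis genes -0.10, G1/S genes 0.073 and G2/M genes 0.11. G2/M genes had 0.17 without 3 cells with unusually many genes. Thinned cells gave -0.14 for mitochondrially encoded genes and 0.32 for immediate early genes. Members over 20 CPM gave 0.11 for the ATF4 list, 0.015 for interferon and 0.30 for immediate early genes, and no filter gave 0.11 for the ATF4 list. Without the cells of unusual mitochondrial share, mitochondrially encoded genes had 0.015 and early G1 genes 0.30.

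With each cell left out in turn, list medians ranged from -0.063 to 0.32 for ATF4, 0.056 to 0.75 for interferon, -0.22 to -0.11 for ribosomal proteins, -0.28 to 0.38 for mitochondrially encoded, -0.12 to 0.72 for immediate early, -0.14 to 0.097 for G1/S, -0.087 to 0.26 for G2/M and 0.36 to 1.02 for early G1 genes.

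Genes detected per cell had medians of 5491 in control and 5496 in dasatinib at a TPM of at least 10. The share of cells with G2/M genes was 100.0% in both groups without thinning or without the cells of unusual mitochondrial share. It was 100.0% in control when 25% of the list was required and 97.8% in dasatinib; when 50% was required it was 90.6% in control and 86.96% in dasatinib, and at a TPM of at least 10 it was 93.9% and 86.96%. For G1/S genes it was 84.4% in control and 86.96% in dasatinib when 50% was required, and 84.8% and 89.1% at a TPM of at least 10, so the order of the groups was the other one. It was 100.0% in both groups without thinning and 100.0% in control and 93.02% in dasatinib without the cells of unusual mitochondrial share. The mitochondrial share was 11.1% in control and 10.5% in dasatinib as a mean over cells, 11.1% and 7.29% with the stricter filter, 12.5% and 11.5% of TPM, and 7.12% and 7.58% without the cells of unusual share.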

Other observations

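The list medians over all or thinned cells were planned, and the genes, cells and other tests in this part were chosen only after the results were seen. Some genes differed between the groups across many cells. In 29 control and 43 dasatinib cells, without the 7 cells of unusual mitochondrial share, splicing kinase CLK1 had a mean log2(TPM + 1) of 3.61 ± 2.49 (SD) in control and 5.54 ± 1.81 in dasatinib. It was detected in 71.4% and 93.02% of these cells after thinning, which left 28 control cells. The tubulin-binding gene TPPP3 had 2.98 ± 2.89 and 4.54 ± 3.15, PRRC1 2.37 ± 2.06 and 3.89 ± 1.88, and the transcription factor SP3 2.14 ± 1.94 and 3.41 ± 1.82. TPPP3 overlaps a small nuclear RNA pseudogene. Lower in dasatinib were the serum and glucocorticoid regulated kinase SGK1 (5.48 ± 1.94 and 3.71 ± 2.64), the stress gene GADD45A (4.73 ± 1.26 and 3.001 ± 2.29), ASB13 (2.83 ± 2.16 and 1.198 ± 1.998), RAD51C, a recombinase paralog of DNA repair (6.63 ± 1.34 and 5.10 ± 2.73), and ULBP2, a ligand of an activating receptor of natural killer cells (3.48 ± 2.38 and 1.98 ± 2.54). Each difference was smaller than the sum of both SDs, which describe the spread over cells and not the error of a difference. The genes were picked because they differ, and each group is 1 sample, so these values are no test.

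Several cells of both groups stood apart by single genes or list scores. Dasatinib cell 26 had PAX4, a transcription factor of endocrine cells, at 3627 TPM, against 1.62 TPM in the next highest dasatinib cell and 0.55 TPM at most in control. In the same cell HEPACAM2 was at 2329 TPM, HES6 at 3071 TPM, TFF3 at 2795 TPM and CDKN1C at 759 TPM, and its G2/M score was 1.27 against a group median of 4.20. Dasatinib cell 47 (0.998) and control cell 40 (1.18) had lower G2/M scores. The enteroendocrine score of dasatinib cell 26 was 0.47, close to the 0.43 of control cell 45. Its goblet score of 0.94 lay below the group median of 1.15, so these lists do not assign it a cell type. Dasatinib cell 34 was the 1 cell of its group with ATOH1 above 0 (13.8 TPM), with AGR2 at 2553 TPM and AGR3 at 819 TPM, and ATOH1 was 0 in control. AGR3 reached 541.2 TPM in another dasatinib cell and 336.0 TPM in control, and AGR2 1009 and 674 TPM. In dasatinib cell 3, ADM was at 5283 TPM, DDIT3 at 2232 TPM, PPP1R15A at 1477 TPM and CCNL1 at 5721 TPM, against group medians of 0.0, 0.81, 5.87 and 68.0 TPM in the other cells. The highest control values were 27.6, 1695, 69.9 and 700.1 TPM, so DDIT3 is not particular to cell 3. Control cell 52 had MLKL at 233 TPM and RIPK3 at 113.4 TPM, with medians of 5.67 and 0.0 TPM in the other control cells. Control cell 45 had a goblet score of 2.96, against 2.41 at most in dasatinib. The drug efflux and detoxification score was 4.95 in control cell 36, against 3.64 at most in dasatinib.

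Interferon-stimulated genes had a median log2 ratio of 0.57, although their summed level was 1330 CPM in control and 1303 CPM in dasatinib. Members over 20 CPM had a median of 0.015 at percentile 63.2, with 5 of 10 higher. The median of the list score over cells was lower in dasatinib by a difference of -0.14. The mean score was 2.41 ± 0.76 (SD) in control and 2.46 ± 0.96 in dasatinib. Both differences lay within the spread over cells, so the scores show no higher level in most treated cells but cannot exclude a small one. The median log2 ratio without dasatinib cell 46, the cell with the highest score, was 0.056 (percentile 61.4). Leaving out the highest cell of 1 group alone lowers its values whatever the cause, so this value is no test. Dasatinib cell 46 had IFI44 at 688 TPM, OAS1 at 838 TPM, IFIT1 at 382 TPM and ISG15 at 5356 TPM, and dasatinib cell 16 had IFITM1 at 989 TPM. Leaving out the highest cell of each group, which replaced an earlier test that left out dasatinib cells alone, gave 0.12 (percentile 74.7). Without the 2 highest of each it was -0.040 (percentile 31.6), so the higher list median rested on few cells. Why these genes were high in dasatinib cells 46 and 16 was not tested and stays open.

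Early G1 and quiescence genes were higher in dasatinib (0.46). No 1 cell accounts for this, since the lowest value with each cell left out was 0.36 (percentile 99.3, without control cell 52), and unequal depth is argued against by 0.42 with every cell thinned to the same depth. The list score of 3 dasatinib cells (26 at 4.47, 46 at 3.96 and 87 at 3.78) lay above the highest control cell (3.55). This list was not examined without the highest cells of each group, so a few cells together may carry part of it. Without the cells of unusual mitochondrial share the median was 0.30 at percentile 96.8, between the limits set for this test, so a part played by those cells stays open. With 0 control libraries numbered inside the dasatinib range, separate preparation of the groups and the treatment cannot be told apart. An effect of dasatinib is a hypothesis that these data leave open.

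Dasatinib cell 87 held 0.020% mitochondrial counts. Its 4996261 counts argue against too few reads, MALAT1 at 3.17 TPM (455 TPM or more in the other dasatinib cells) against a nucleus, and the low level of 40 genes for secreted and membrane proteins (-5.40, log2 against the other dasatinib cells) against a loss of mitochondrial reads alone. The median of these genes minus that of 41 genes for cytosolic proteins was -5.92, against -0.87 or more in the other 45 dasatinib cells, with the cytosolic genes at 0.52. A candidate explanation is that the library holds mainly free cytosolic RNA, as from a cell that leaked before its organelles broke open. The test was revised once, because the level of the secreted and membrane genes alone was lower in dasatinib cell 47 (-6.30), a cell low in both kinds of genes.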
